A study of Homo sapiens with 4 samples.

How the data were processed

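RNA-seq was carried out on DU145, an established prostate cancer cell line, in 4 libraries. Per the labels, 2 libraries came from control cells with pLKO, a lentiviral vector for short hairpin RNAs, and 2 from cells with TAZ knockdown. The series states that 2 independent TAZ hairpins were used, and the labels do not say which knockdown library carries which. Cells were grown with 10% fetal bovine serum. Per the labels' protocols, 0.2 µg of RNA per sample was used, mRNA was captured on poly-T beads, and the kit as described does not mark strand, so reads from a gene and an overlapping antisense gene cannot be told apart. Nothing in the labels says that libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Within the knockdown group that spread also holds any difference between hairpins.

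The deposited table holds, per gene symbol, the signal of each library in the form of normalized read counts, together with the columns of a DESeq2 results table. Per the file headers, the authors' columns are a mean signal over the 4 libraries, a log2 fold change with its standard error, a score (the Wald statistic), and a p-value with its adjusted p-value. STAR, DESeq2 and hg19 are named in the submitters' processing notes, with no version or role. The annotation and the read counter are not given in the sources used here. Reference transcripts were from another build (GRCh38, GENCODE 29), so no coordinates are printed. In each library, 100% of the deposited values were whole multiples of the smallest value above 0 (within 0.001 reads), so reads per gene were recovered by dividing by that step. Recovered totals were 13681392 reads in control 1, 11687727 in control 2, 14814918 in knockdown 1 and 12078623 in knockdown 2. Of 19897 rows, 26 carried symbols converted to dates and were left out. They held 0.153 to 0.191% of the reads of a library. A further symbol stood on more than 1 row and is not named.

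The design fixed before the data were examined assumed raw counts and edgeR. It named limma on log2(value + 1) for a table of normalized values, and that fit gave the main results. Genes entered when the deposited value was at least 1 in at least 2 libraries, which left 17737 rows. limma (version 3.58.1, R 4.3.3) was run with eBayes and an intensity trend, without a replicate block, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates changes of low genes. Count models on the recovered reads were alternatives: edgeR's quasi-likelihood test (version 4.0.16), DESeq2's Wald test (version 1.42.0) and limma-voom.

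Of 28 gene lists written before the data were examined, 27 had at least 5 tested members and were tested with limma's camera on the same log2 values, with a preset correlation of 0.01. The list of mitochondrial transcripts was not analysed here. Each test was repeated with an estimated correlation and with fry. Members past the threshold were counted over all genes tested and adjusted over the list alone. Over-representation of lists among the genes called in the authors' deposited table was tested with one-sided Fisher's exact tests (54 tests against 12673 genes with an adjusted p), an analysis chosen after the data were seen.

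Genes were named by a rule written before the data were examined. It covered WWTR1, TAZ, YAP1 and 10 fixed genes (CYR61, CTGF, ANKRD1, AMOTL2, AXL, CDH1, VIM, CDKN1A, CCND1 and MYC). It also covered the 10 largest changes each way among genes past the threshold with a mean of at least the median of tested genes and both knockdown libraries on the same side of both controls. From each list it took up to 4 passing members, or the 2 with the smallest p. The part on largest changes was also applied to the authors' deposited table after the data were seen. Other members named because they passed when adjusted over their list alone, and genes that differed between the knockdown libraries, were chosen after their values were seen. One gene of that last group is not reported here.

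Agreement of the knockdown libraries was measured as the correlation across genes of 2 differences with no shared control. Their difference was tested in a fit with 3 groups, in which the spread comes from the controls alone. Transcript length and GC content were taken from the longest protein-coding transcript per gene and were found for 14583 of the 17737 tested rows. After a trend with length had been seen, each library's spline trend with length and GC content (4 degrees of freedom each) was removed in added alternatives. The share of a list's median and mean kept after removal was given a 95% interval by bootstrap over its members (2000 resamples).

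Alternatives chosen before the data were examined were another scaling, filter, pseudocount or count model, a replicate block, and leaving out each library in turn. Where a group kept 1 library, it was assumed to vary like the other group. The fits were tested on 5 simulated data sets with the real means and depths, 2 libraries against 2. In each, 200 genes with a mean count of at least 50 were changed, in equal numbers by 2-fold and 4-fold. For the comparison of TAZ knockdown with control, limma on about 17723 genes recovered 61.8% of 2-fold and 99.2% of 4-fold changes. DESeq2 on about 19305 genes recovered 63.6% and 98.2%. The simulated noise was independent between genes, without shifts shared by many genes of a library, so these rates may overstate the power in the real data.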

Results

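The transcriptome of DU145 prostate cancer cells was measured by RNA-seq in 2 control libraries with the empty hairpin vector and 2 libraries with TAZ knockdown. The table gave normalized read counts, and the reads recovered from it numbered 11687727 to 14814918 per library. By its title, the series asked which genes TAZ controls in prostate cancer cells. TAZ is a transcriptional coactivator of the Hippo pathway encoded by WWTR1. The row named TAZ belongs to tafazzin, a gene whose older symbol was TAZ and whose protein acts in mitochondria.

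WWTR1 fell in both knockdown libraries. Its normalized count was 2508 and 3626 in the controls and 839 and 719 in the knockdown libraries, a mean of 3067 ± 790 (SD, n = 2) against 779 ± 84.4 (SD, n = 2), or 25.4% of control. The log2 fold change was -1.96 ± 0.20 (SE), with a limma adjusted p of 0.0086. The tafazzin row TAZ had 170 ± 36.7 and 138 ± 30.9 counts (SD, n = 2 each) and did not pass the test (limma adjusted p = 0.849). YAP1, the paralogous coactivator, had 2616 ± 238 in controls and 2532 ± 190 in knockdown (SD, n = 2 each), with a limma adjusted p of 0.975. Without any 1 library the log2 fold change of WWTR1 stayed between -2.22 and -1.69, but its limma adjusted p rose to between 0.308 and 0.9999.

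**Figure D1:**
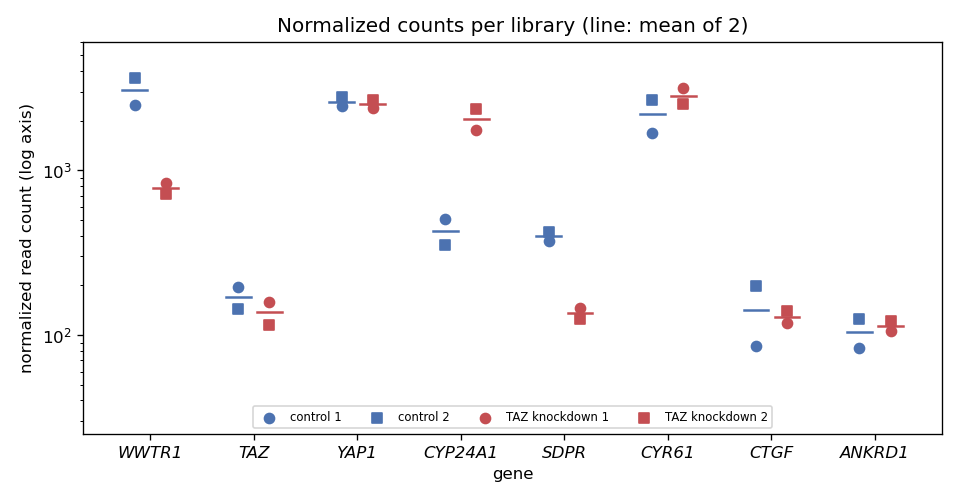
Normalized read counts (log axis) of 8 genes in each library, with controls in blue, TAZ knockdown in red and a line at the mean of 2 libraries. WWTR1 lay at 839 and 719 in the knockdown libraries against 2508 and 3626 in the controls, whereas the values of the YAP/TAZ targets CYR61, CTGF and ANKRD1 overlapped between groups.

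Across all genes, limma called 1 gene higher and 1 lower. The gene that rose was CYP24A1, which encodes the enzyme that inactivates vitamin D. Its count went from 430 ± 107 to 2056 ± 418 (SD, n = 2 each), 4.78-fold, with a log2 fold change of 2.26 ± 0.21 (SE) and a limma adjusted p of 0.0086. The gene that fell was WWTR1. edgeR and limma-voom on the recovered reads each called the same numbers, 1 higher and 1 lower. DESeq2 on the recovered reads called 57 higher and 11 lower, as did the authors' deposited table, and the 68 genes were shared. An unadjusted limma p under 0.05 was reached by 1251 genes, where 887 would be expected by chance, and an unadjusted DESeq2 p under 0.05 by 826, where 994 would be. The 994 covers all 19871 genes tested, including 7320 that DESeq2 gave no adjusted p, so it may overstate the chance number. Both knockdown libraries lay on the same side of both controls for 37.4% of tested genes, against 33.3% by chance. The DESeq2 count of 68 was 4 without knockdown 2 (3 shared) and 12 without control 1 (9 shared). It was 79 without control 2 (26 shared), and 80 without knockdown 1 (29 shared), where 35 genes were higher and 45 lower. limma called 0 genes without any 1 library.

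Among called genes with a mean count of at least the median of tested genes, the largest increases in the authors' deposited table, besides CYP24A1, were those of STK32A, TNC, LPP, ST14, MYL9, SPOCD1, LNPEP, LONRF2 and CREB5. TNC encodes the matrix glycoprotein tenascin-C, and its count went from 5156 ± 210 to 12065 ± 2568 (SD, n = 2 each), with an adjusted p of 4.0e-06 in the authors' deposited DESeq2 table. MYL9, a myosin regulatory light chain, went from 1928 ± 61.9 to 4134 ± 230, and LPP, a focal adhesion protein, from 2769 ± 104 to 6081 ± 463 (SD, n = 2 each). ST14, the membrane protease matriptase, went from 193 ± 17.7 to 472 ± 71.2 (SD, n = 2 each). Within the same limit on the mean count, the largest decreases after WWTR1 were those of SDPR, SLC22A31, IFIT1, IFIT2, IFITM2, CST6, SMOX and BNIP3. SDPR, a caveola protein, went from 398 ± 37.7 to 136 ± 14.9 counts (SD, n = 2 each), with an adjusted p of 1.1e-05 in the authors' deposited DESeq2 table. None of these genes other than CYP24A1 and WWTR1 passed limma over all genes. The limma adjusted p was 0.0877 for SDPR, LPP and MYL9 and 0.128 for TNC. With a trend with transcript length and GC content removed, DESeq2 still called CYP24A1, WWTR1, STK32A, TNC, ST14, MYL9, SPOCD1 and IFIT2, but not LPP, LNPEP, LONRF2, CREB5, SLC22A31, IFIT1, IFITM2, CST6, SMOX or BNIP3, and SDPR had no length. Most of the log2 fold change stayed in the genes whose call ended, at 62.9% for LPP (1.13 ± 0.18 to 0.71 ± 0.19, SE) and 74.2 to 95.2% for the others except IFIT1. BNIP3 went from -0.73 ± 0.19 to -0.69 ± 0.19 and CREB5 from 1.32 ± 0.32 to 1.07 ± 0.31 (SE). The fold change of IFIT1 went from -1.48 ± 0.37 to -1.60 ± 0.73 (SE), its call ending with the larger error.

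Genes of integrins, focal adhesions and the actin cytoskeleton were higher as a group after TAZ knockdown. Of 35 members, 29 had a higher mean, 20 were above both controls in both knockdown libraries, and the median log2 fold change was 0.44. The list passed camera with an adjusted p of 7.0e-11, and had an adjusted p of 0.483 with an estimated correlation. Over all genes tested 0 members passed limma, and adjusted over the list alone 11 did, all higher. These were MYL9, ITGA1, ITGAV, CNN2, TPM4, VCL, ITGA2, TPM1, CALD1, ITGB8 and ITGB1. ITGA1, a collagen-binding integrin subunit, went from 58.7 ± 4.91 to 168 ± 11.1 and VCL, the focal adhesion protein vinculin, from 3985 ± 218 to 6332 ± 311 (SD, n = 2 each). Of the genes called higher in the authors' deposited table, 6 were on this list (Fisher's exact test, one-sided, adjusted p = 2.8e-07). That test treats genes as independent, and its calls come from the same libraries as the camera result, so it adds no separate support. Of these 6, MYL9, CNN2 and TPM4 were still called by DESeq2 with the length and GC trend removed, and ITGA1, ITGAV and VCL were not (DESeq2 adjusted p = 0.153, 0.0601 and 0.299), although 80.4, 78.5 and 79.9% of their log2 fold changes stayed. The list stayed past camera without each library in turn, but without control 1 its median was 0.26.

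Epithelial junction and keratin genes were split. Of 30 members, 20 had a higher mean and the median log2 fold change was 0.41. The list passed camera with an adjusted p of 8.3e-04, and had an adjusted p of 0.483 with an estimated correlation. Over all genes tested 0 members passed limma, and adjusted over the list alone 7 were higher and 2 lower. The higher members were ST14, SPINT1, CDS1, CLDN7, ESRP1, OVOL2 and CLDN1, which include protease and protease inhibitor, tight junction and epithelial splicing genes. The lower ones were KRT8 and KRT18, which encode the paired keratins of simple epithelia. KRT8 had 21719 ± 4561 counts in controls and 11551 ± 4337 in knockdown (SD, n = 2 each). SPINT1, an inhibitor of matriptase, had 656 ± 20.3 and 1255 ± 96.2 (SD, n = 2 each). CDH1, which encodes E-cadherin, had 1074 ± 360 and 1826 ± 666 (SD, n = 2 each), and did not pass (limma adjusted p = 0.650). Without control 1 the list did not pass camera (adjusted p = 0.0595, median 0.21), and without knockdown 2 its median was 0.17.

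Mesenchymal, TGF-beta response and extracellular matrix genes had smaller medians of 0.10, 0.19 and 0.09 on the log2 scale. All 3 lists passed camera as higher, with adjusted p of 0.0219, 0.0207 and 0.0435. With an estimated correlation their adjusted p-values were 0.618, 0.483 and 0.601. Adjusted over the list alone, TNC, TAGLN and FN1 passed in the mesenchymal list, LTBP1 and TGFBI in the TGF-beta list and TNC in the matrix list, all higher, while 0 passed limma over all genes tested. VIM, which encodes vimentin, had 22135 ± 2299 counts in controls and 18608 ± 440 in knockdown (SD, n = 2 each) and did not pass (limma adjusted p = 0.815). COL12A1, a fibril-associated collagen, had 655 ± 97.0 and 1052 ± 19.5 (SD, n = 2 each), with a limma adjusted p of 0.412. Without control 1 none of the 3 lists passed camera (adjusted p = 0.160 to 0.825). Without knockdown 1 the TGF-beta and matrix lists did not pass (camera adjusted p = 0.0792 and 0.306), and without knockdown 2 the mesenchymal and TGF-beta lists did not (camera adjusted p = 0.0719 and 0.0589). The medians moved with single libraries. The mesenchymal median was 0.05 without control 1, 0.24 without control 2, 0.33 without knockdown 1 and 0.16 without knockdown 2. The matrix median was 0.01 without control 1, 0.25 without control 2 and -0.01 without knockdown 1, and the TGF-beta median was 0.0034 without control 1.

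Interferon-induced genes were lower as a group. Of 37 members, 36 had a lower mean, 19 were below both controls in both knockdown libraries, and the median log2 fold change was -0.75. The list passed camera with an adjusted p of 2.8e-15, and had an adjusted p of 0.601 with an estimated correlation. Over all genes tested 0 members passed limma, and adjusted over the list alone 10 did, all lower (IFITM2, IFIT2, OASL, IFITM1, IFIT1, IFI44, IFITM3, ISG20, IRF7 and IFIT3). IFIT2, an antiviral RNA-binding protein, went from 404 ± 123 to 178 ± 12.3, and IFIT1 from 540 ± 323 to 195 ± 62.9 (SD, n = 2 each). The IFITM genes are closely similar copies, and how reads matching several genes were counted is not given in the sources used here, so their separate values are uncertain. The controls differed from each other, with a median log2 difference of -0.73 for control 2 minus control 1. Without control 1 the list median was -0.32 and the camera adjusted p 0.0318, and without knockdown 2 the median was -0.40.

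Ribosomal protein genes were lower by a small amount, with 38 of 38 members lower in the mean, 36 below both controls in both knockdown libraries, and a median log2 fold change of -0.35. The list passed camera with an adjusted p of 1.2e-15, and had an adjusted p of 0.601 with an estimated correlation. The median difference from the controls was -0.22 and -0.25 in knockdown 1 and -0.44 and -0.48 in knockdown 2. RPS18 had 17454 ± 387 counts in controls and 12557 ± 1870 in knockdown (SD, n = 2 each), and 0 members passed limma over all genes or adjusted over the list alone. These genes have many processed pseudogenes of similar sequence, so single values are uncertain for the same reason. MYC-regulated growth genes had a median of -0.25 and passed camera as lower (adjusted p = 6.5e-05; adjusted p = 0.669 with an estimated correlation). Without control 2 the camera adjusted p of the MYC list was 0.977 and without knockdown 2 it was 0.307, with a median of -0.04 in both fits, while the median was -0.46 without control 1 and -0.42 without knockdown 1. MYC had 2094 ± 647 and 1760 ± 98.9 counts (SD, n = 2 each), with a limma adjusted p of 0.860.

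Hypoxia and glycolysis genes were lower (median -0.26, camera adjusted p = 2.9e-04; adjusted p = 0.483 with an estimated correlation), and did not pass without knockdown 1 (camera adjusted p = 0.0990, median -0.16). BNIP3, a mitophagy receptor induced by hypoxia, passed adjusted over the list alone and went from 3977 ± 504 to 2404 ± 102 counts (SD, n = 2 each). Sterol synthesis genes were higher (median 0.21, camera adjusted p = 0.00104; adjusted p = 0.483 with an estimated correlation), and did not pass without control 1 (camera adjusted p = 0.0682, median 0.12). LSS, which encodes lanosterol synthase, had 642 ± 19.5 and 1051 ± 302 counts, and SREBF1 had 1029 ± 177 and 685 ± 195 (SD, n = 2 each), and neither passed limma.

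**Figure D2:**
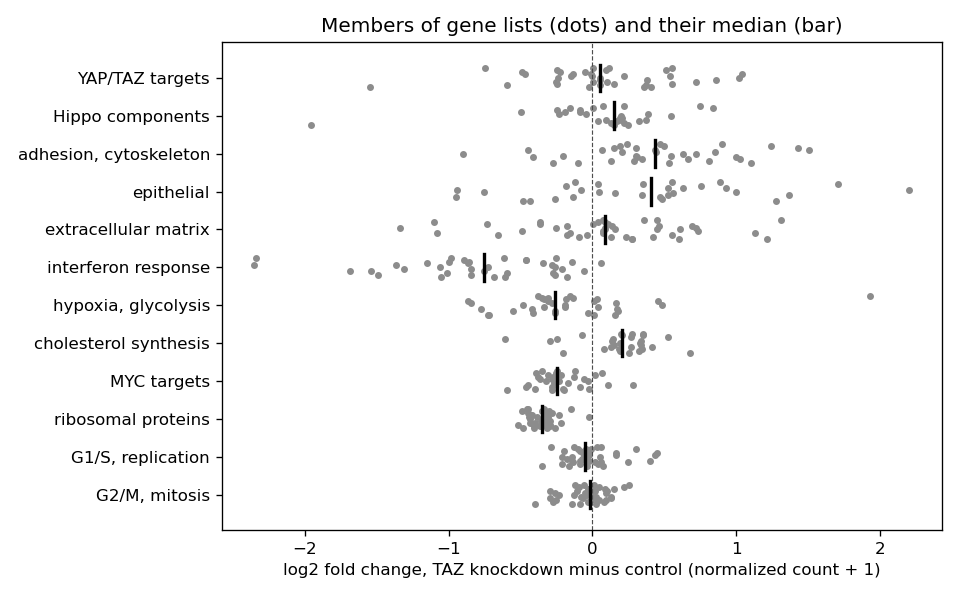
Log2 fold changes (TAZ knockdown minus control, normalized count + 1) of the members of 12 gene lists as dots, with the median of each list as a bar. Ribosomal protein genes lay close to their median of -0.35, interferon genes around -0.75, and adhesion and cytoskeleton genes around 0.44, while the YAP/TAZ target list was centred at 0.05.

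Known targets of the TAZ/YAP1-TEAD complex had no common direction against both controls. Of 38 members, 22 had a higher and 16 a lower mean, with a median log2 fold change of 0.05 (camera adjusted p = 0.461). Their median difference was 0.29 and 0.16 from control 1 in knockdown 1 and 2, and -0.04 and -0.13 from control 2. It was 0.37 for control 2 minus control 1, so the controls lay too far apart to tell whether the list changed. SDPR passed adjusted over the list alone, lower, and 0 members passed limma over all genes tested. CYR61 had 2190 ± 718 counts in controls and 2840 ± 440 in knockdown, CTGF 142 ± 80.4 and 129 ± 15.5, and ANKRD1 104 ± 28.8 and 113 ± 10.98 (SD, n = 2 each). AMOTL2 had 2886 ± 699 and 3074 ± 9.55, and AXL 11144 ± 1033 and 9354 ± 469 (SD, n = 2 each). The limma adjusted p of these 5 genes was 0.737 to 0.994. RBMS3 had 44.7 ± 0.24 and 93.0 ± 6.23 (SD, n = 2 each; limma adjusted p = 0.539). Hippo pathway components had a median of 0.15 (camera adjusted p = 0.461), and WWTR1 was the member past the threshold. The medians moved with single libraries. For targets and components they were 0.15 and 0.20 without control 2, -0.12 and 0.04 without control 1, 0.04 and 0.06 without knockdown 1, and 0.08 and 0.11 without knockdown 2.

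Cell cycle genes had medians near 0, at -0.05 for the G1/S list and -0.02 for the G2/M list (camera adjusted p = 0.507 and 0.461). MCM2, a replicative helicase subunit, had 4134 ± 17.0 and 3239 ± 142 counts, and AURKA, a mitotic kinase, 1483 ± 239 and 1122 ± 188 (SD, n = 2 each). CCND1, which encodes cyclin D1, had 12130 ± 5785 and 11693 ± 4902, and CDKN1A, the cell cycle inhibitor p21, 1300 ± 384 and 1952 ± 377 (SD, n = 2 each). None of the 4 passed limma (adjusted p = 0.651 to 0.994). The G2/M list was lower without control 2 (camera adjusted p = 3.1e-05) and higher without control 1 (camera adjusted p = 0.0122), so its direction rested on which control was used. The G1/S median also turned, at -0.13 without control 2 and -0.10 without knockdown 2, but 0.09 without control 1 and 0.01 without knockdown 1.

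Several lists had smaller or uneven changes. EGFR-MAPK response genes (median 0.19) and markers of stem-like prostate cancer cells (median 0.15) passed camera as higher, with adjusted p of 0.0136 and 0.0294, and had adjusted p of 0.712 and 0.483 with an estimated correlation. The EGFR-MAPK list was lower without control 1 (camera adjusted p = 0.0341, median -0.25) and did not pass without knockdown 1 (camera adjusted p = 0.0808, median 0.10), and its median was 0.66 without control 2. The stem-like list did not pass without control 1 or knockdown 1 (camera adjusted p = 0.728 and 0.308), and its median was 0.02 without control 1, 0.23 without control 2 and 0.29 without knockdown 2. The camera adjusted p was 0.461 for p53 targets, 0.247 for the integrated stress and unfolded protein responses, 0.276 for beta-catenin targets, 0.380 for apoptosis regulators and 0.506 for NF-kappaB and inflammatory genes, so none of these passed. Without control 2 the beta-catenin targets were higher and the NF-kappaB list lower (camera adjusted p = 0.00665 and 0.0199). Without knockdown 2 the beta-catenin targets were higher and apoptosis regulators lower (camera adjusted p = 0.0280 and 0.0326). For cell type markers it was 0.507 for luminal and androgen receptor genes, 0.486 for basal, 0.598 for neuroendocrine and 0.288 for fibroblast genes. Basal genes passed as higher without control 2 and fibroblast genes without knockdown 2 (camera adjusted p = 0.00821 and 0.0497). Of markers of leukocytes and endothelium, 7 were tested at low counts and passed as lower (median -0.85, camera adjusted p = 0.0309; adjusted p = 0.618 with an estimated correlation), but not without control 2 or knockdown 2 (camera adjusted p = 0.242 and 0.118, medians -0.49 and -0.39), and the median was -1.31 without knockdown 1. Replication-dependent histone genes, whose mRNAs lack poly(A) tails, were higher (median 0.48, camera adjusted p = 9.8e-04; adjusted p = 0.483 with an estimated correlation), and did not pass without control 1 or knockdown 1 (camera adjusted p = 0.0508 and 0.128, medians 0.34 and 0.25).

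Differences between knockdown and control libraries followed transcript length. Among 10675 genes with a mean count of at least 50, Spearman's rho across genes between the log2 difference and transcript length was 0.22 to 0.38 in the 4 knockdown-minus-control pairs, 0.16 for control 2 minus control 1 and 0.09 for knockdown 2 minus knockdown 1. For GC content it was -0.39 to -0.10 in those pairs, -0.18 between the controls and -0.23 between the knockdown libraries. Genes are not independent replicates. The median transcript length was 6386 bases for genes called higher in the authors' deposited table and 2694 for those called lower, against 3553 for the 10675 genes. With the length and GC trend removed, an analysis chosen after the data were seen, DESeq2 called 20 genes higher and 3 lower (21 shared with the 68).

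**Figure D3:**
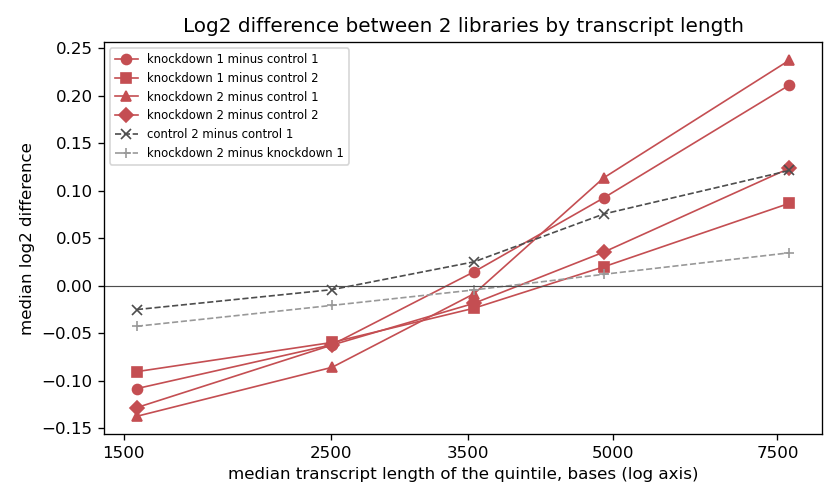
Median log2 difference between 2 libraries (vertical axis) in 5 equal groups of genes ordered by transcript length (horizontal log axis, bases), one line per pair of libraries. All 4 knockdown-minus-control pairs (red) rose with length, from between -0.14 and -0.09 to between 0.09 and 0.24, control 2 minus control 1 (dark dashed) rose from -0.03 to 0.12, and knockdown 2 minus knockdown 1 (light dashed) went from -0.04 to 0.03.

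The 2 knockdown libraries lay about as close to each other as the controls did, with an SD of the log2 difference across genes of 0.63 against 0.67. Their differences from separate controls were weakly correlated. With no shared control, the differences of knockdown 1 from control 1 and knockdown 2 from control 2 had a Pearson r of 0.04 across 17737 genes, and 0.08 with the controls swapped. At 5 CPM or more in 2 libraries these were 0.13 and 0.26. A fit of knockdown 2 against knockdown 1 compared these 2 libraries only, with each assumed to vary like the controls. In it limma called 0 genes (524 at an unadjusted p under 0.05, where 887 would be expected by chance), edgeR 15 and DESeq2 10. Genes with higher counts in knockdown 2 among the DESeq2 calls were PI3, DMBT1 and IVL, which include an epithelial protease inhibitor and involucrin. Those with lower counts included MDK, SLC7A5, SUSD2, DDAH1, AQP3 and SYT12. PI3 had 71.4 and 85.1 counts in the controls, 65.5 in knockdown 1 and 617 in knockdown 2. SLC7A5, an amino acid transporter, had 6466 and 8910 in the controls, 6779 in knockdown 1 and 1816 in knockdown 2.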

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

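edgeR with TMM was the main test the design named for raw counts, and its use as an alternative on recovered reads came after the data were seen. Other alternatives chosen after the data were seen were the authors' deposited table, all crossed blocks and the edgeR and DESeq2 blocks. So were the length and GC corrections with their reference fits, and every DESeq2 setting other than the default one. limma called 1 gene higher and 1 lower. TMM scaling, total counts, no filter, a 5 CPM filter, edgeR with TMM or RLE, limma-voom and the length and GC correction also gave 1 and 1. A pseudocount of 0.1 and edgeR with total counts gave 0 and 0, and so did each fit without 1 library (0 to 0). DESeq2 and the authors' deposited table gave 57 and 11. With the replicate number as a block, limma gave 4 and 3, edgeR 4 and 3, and DESeq2 21 and 5. The correlation of same-numbered deviations was -0.04 across tested genes and -0.12 at 5 CPM or more, so the numbers did not pair the libraries. Crossed pairing was run although only the second value is below -0.1, and gave 156 and 85 in limma, 1 and 1 in edgeR and 33 and 8 in DESeq2. The cause of these differences was not tested.

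In DESeq2, the 57 higher and 11 lower became 20 and 3 with the length and GC trend removed, 56 and 12 with a 5 CPM filter, and 58 and 10 over genes with a length. Without 1 library they were 2 to 63 higher and 2 to 45 lower: 8 and 4 without control 1, 63 and 16 without control 2 (26 of 79 shared with the 68), 35 and 45 without knockdown 1 (29 of 80 shared), and 2 and 2 without knockdown 2.

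The WWTR1 log2 fold change kept its direction in all 21 alternatives, at -2.22 to -1.53, with a lowest adjusted p of 1.8e-14 in DESeq2. The value of -1.53 is the shrunken one of the authors' deposited table, and DESeq2 without shrinkage gave -1.98. WWTR1 missed the threshold with a pseudocount of 0.1 (log2 -1.96, limma adjusted p = 0.0644) and with edgeR on total counts (log2 -1.95, edgeR adjusted p = 0.0527). It also missed it without each library (log2 -2.22 to -1.69). CYP24A1 missed it in the same settings. Of 72 other named genes, 6 changed sign in some setting, none of them called by limma.

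All 14 list calls were lost with an estimated correlation (lowest adjusted p 0.483) and with fry (lowest 0.458). Over the 14 lists the estimated correlation ran from -0.0040 (TGF-beta) to 0.83 (ribosomal proteins), against the preset 0.01. It was 0.79 for the MYC list, 0.66 for interferon, 0.52 for EGFR-MAPK and 0.25 for adhesion. Where it lay far above the preset, the camera p at the preset may be far too small. With so few libraries, fry and the estimated-correlation test may have had little power, which was not measured. These losses therefore do not decide whether a list changed. After the trend was removed 12 of the 14 held, without the matrix and stem-like lists (camera adjusted p = 0.0679 and 0.0617). Over the same genes with the trend kept, the matrix list also missed the threshold (camera adjusted p = 0.0602). Without 1 library, 6 held without control 1, 12 without control 2, 8 without knockdown 1 and 10 without knockdown 2. The adhesion, interferon and ribosomal protein lists passed in all 4 such fits. A direction changed in some setting for 11 lists. The G2/M list turned to higher and the EGFR-MAPK list to lower without control 1 (camera adjusted p = 0.0122 and 0.0341). Without 1 library their camera adjusted p spanned 3.1e-05 to 0.742 and 5.3e-11 to 0.0808. The replicate block changed no list call.

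The correlation between the knockdown libraries was 0.04, and 0.0808 with controls swapped, 0.13 at 5 CPM or more and 0.02 with the trend removed. The count of genes that differed between them was 0 in limma, 6 with a 5 CPM filter, 15 in edgeR with TMM or RLE and 10 in DESeq2. DESeq2 gave no adjusted p to 7320 genes, and whether depth limited their calls was not tested.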

Other observations

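The tests of single libraries, the MRTF-SRF test and the bootstrap intervals of the share of a median or mean kept were chosen after the results they bear on had been seen. Outside the lists, the authors' deposited table called several genes higher, of which RSPO3, GALNT3 and PRUNE2 had counts in knockdown 2 well above those in knockdown 1. RSPO3, a Wnt signal enhancer, had 44.5 and 41.4 counts in the controls, 147 in knockdown 1 and 412 in knockdown 2. GALNT3, a mucin-type glycosyltransferase, had 24.1 and 25.3, then 97.4 and 320.0, and PRUNE2 14.8 and 10.4, then 42.5 and 192. CACNG4, a calcium channel subunit, did not differ in this way and had 7.42 and 9.20 in the controls and 55.8 and 56.3 in the knockdown libraries. These genes were singled out after their values were seen.

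The higher adhesion and cytoskeleton genes and the excess of higher over lower DESeq2 calls were weighed against a trend with transcript length and GC content. After the trend was removed, the adhesion list had a median log2 difference of 0.355, kept its sign in the 4 library pairs (0.20 to 0.54, against 0.19 between the controls), and passed camera (adjusted p = 2.1e-11; adjusted p = 0.559 with an estimated correlation), which argues against the trend as the whole cause. It also passed without knockdown 2 (camera adjusted p = 6.28e-09). The share of DESeq2 calls that were higher was 87.0% of 23 after removal, and with the trend kept it was 43.75% of 80 without knockdown 1 and 2 of 4 without knockdown 2. For the epithelial list the median after removal was 0.348 and camera gave an adjusted p of 2.6e-05 (adjusted p = 0.559 with an estimated correlation). The pairs of knockdown 1 and knockdown 2 with control 2 (0.25985 and 0.18) lay below the difference between the controls (0.26017). The test written beforehand therefore did not exclude the trend, and the share of the median kept had a bootstrap 95% interval of -75.0 to 371%. The mean, examined after both outcomes were seen, went from 0.35 to 0.41, with 117% kept (95% interval 101 to 172%). In these libraries the fitted trend thus did not account for the list's mean. The interval resampled members with the libraries held fixed, so it holds no spread between libraries. A difference between the libraries stays open. Without knockdown 2 that list passed (camera adjusted p = 9.15e-04), but with an estimated correlation it did not pass even with all libraries (adjusted p = 0.483).

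The lower interferon genes were weighed against the same trend and against control 1. After removal the median was -0.662 and the list passed camera (adjusted p = 4.9e-15; adjusted p = 0.559 with an estimated correlation), but the pair of knockdown 1 and control 2 stood at -0.03, against -0.72 between the controls, so the test written beforehand did not exclude the trend. A bootstrap over members, added after that outcome was seen, gave 88.2% of the median kept (95% interval 70.1 to 111%). In these libraries most of the list median thus stayed after removal. The interval treats members as independent and the libraries as fixed, so it holds no spread between libraries. Without control 1 the median was -0.321, against -0.751 with all libraries, which is consistent with a high level in that control making up much of the difference, although the list still passed camera (adjusted p = 0.0318; adjusted p = 0.601 with an estimated correlation and all libraries). A lower interferon response after TAZ knockdown stays open as an untested alternative.

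The lower ribosomal protein genes had a median of -0.268 after the trend was removed, with -0.10 to -0.42 in the 4 library pairs and 0.09 between the controls, which argues against the trend as the whole cause. Only this technical explanation was tested. A change in growth after TAZ knockdown may remain as a hypothesis, and with an estimated correlation the list did not pass (adjusted p = 0.559).

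The DESeq2 calls numbered 68 in the real grouping, and 0 and 6 in the other splits of the 4 libraries. Only the real grouping gave that many calls, and 3 splits are too few for a share under 0.05.

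A first hypothesis was that MRTF-SRF, the actin-regulated transcription factor pair, was more active, since MYL9, TAGLN and VCL are among its targets and among the DESeq2 calls. Its list was written after the adhesion list, with which it shares members, had been seen to be higher. The 20 targets outside the calls had a median log2 difference of 0.510 with the trend removed (19 higher), with a camera p of 3.0e-09 at the preset correlation and a p of 0.155 with an estimated correlation. The 11 targets also outside the adhesion list had a median log2 difference of 0.49, with a limma camera p of 3.7e-05 at the preset correlation and a p of 0.215 with an estimated correlation. The first value alone would have met the criterion as first written, and the requirement that both pass was added after it was seen, so the hypothesis is left open.

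A second hypothesis was that the rise of CYP24A1, a textbook target of the vitamin D receptor, reflected higher activity of that receptor. The 12 other targets tested had a median log2 difference of 0.0973, with quartiles of -0.44 and 0.25 and a camera p of 0.863. That gives no sign of a shared increase, and a median near 0 over members that go both ways does not exclude the hypothesis.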
